A study of Mus musculus with 24 samples.

How the data were processed

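The series holds 24 samples of mouse 3T3-L1 cells, a preadipocyte line that turns into fat cells after hormonal induction. 12 RNA-seq libraries make a design of 2 genotype labels (control and LSD1 overexpression) by 2 days (day 0, confluent cells before induction, and day 7), with 3 biological replicates in each of the 4 groups according to the sample titles. 6 chromatin immunoprecipitation (ChIP-seq) samples have a peak list: LSD1 in control cells and in cells labelled as overexpressing LSD1 at each day, and Nrf1 at each day, with 1 sample each. The 6 input samples have no file of their own that was used here. According to the labels, induction used 10 µg/ml insulin, 1 µM dexamethasone, 10 µM rosiglitazone and 500 µM isobutylmethylxanthine, and the medium was changed at day 3. The title of the day 7 Nrf1 sample names LSD1 cells while its genotype label says control, so it was grouped by day and factor without a genotype.

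The RNA-seq files hold raw read counts as deposited, with 1 value per RefSeq transcript and no header. Per the submitters' processing notes, the build was mm10 and the tools were TopHat2 version 2, HOMER, edgeR and DESeq 1.8.3, without a stated role or order. The authors deposited each peak list with a peak score in its last column, whose lowest value was 50.0. Per the submitters' processing notes, the ChIP-seq peaks came from Bowtie2 and from MACS 1.41, the version as written there. The input used for each list, the cut-off and the read depth of the ChIP-seq libraries are not stated, so no interval or test between conditions that needs depth was computed for peaks.

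Each of the 12 count files had 30521 transcript rows. Accessions were named from the RefSeq table of the reference (29144) or from GENCODE tables (177), and 1200 stayed unnamed, with 0.896% of all counts. Transcripts of 1 gene shared reads: of 2527 genes with several transcripts and a mean count of 100 or more, 2362 (93.5%) had a second transcript at 50% or more of the first. Each gene was therefore represented by its transcript with the highest mean count, which left 24346 features. The files held no gene of the mitochondrial genome, so the list of such genes had 0 members and gave no result. Totals over all transcripts were 27512273 to 37565527 counts per library, and the sum with 1 transcript per gene was lower in each. The former counts a read more than once where isoforms share it. Counting intervals and floors cover counting error only, since the reads carry no molecular identifiers.

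Expression was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on the 4 groups, TMM scaling, a robust quasi-likelihood fit of 4 group means to all 12 libraries, and Benjamini-Hochberg adjustment over the 13356 genes tested, with a threshold of 0.05. The comparisons were day 7 against day 0 within each genotype label, the labelled libraries against control at each day, and the interaction (the difference between those differences). All gene tests were two-sided. Levels are in CPM, the depth-scaled count unit of edgeR, with TMM-scaled library sizes. A fold against a group with 0 counts is given as a lower bound with a floor of 3 counts over the group. Against a group with 1 to 3 counts the ratio is given with its exact 95% counting interval (Clopper-Pearson, given the sum of both counts).

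Lists of genes were fixed before the data were examined: adipocyte program, preadipocyte and fibroblast, thermogenic, beige-selective, white-selective, nuclear-encoded oxidative phosphorylation, oxidative phosphorylation genes of the mitochondrial genome, TCA cycle, fatty acid oxidation, lipogenesis, glycolysis, mitochondrial biogenesis, mitochondrial ribosome, cell cycle, LSD1 complexes, interferon response, inflammation, and endoplasmic reticulum stress with the integrated stress response. Markers of macrophages, muscle, bone or cartilage and endothelium were fixed as lists of other cell types. Each list with at least 3 measured members was tested with limma 3.58.1 camera (prior count 2, preset correlation 0.01, two-sided), adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Lists shared a few members, such as Slc2a4 in the adipocyte and glycolysis lists.

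Genes were named by a rule fixed before the data were examined. It took the 10 genes with the largest rise and the 10 with the largest fall in a comparison, among those past the threshold with a mean of at least 10 CPM over the 12 libraries and no overlap between the replicates of the 2 groups. For the interaction, the overlap condition did not apply, and day 7 against day 0 in the labelled libraries contributed list members only. The rule added up to 2 members per list and direction by smallest adjusted p, and always Kdm1a, Nrf1, Pparg, Adipoq, Ucp1, Prdm16, Ppargc1a and Cidea. For peaks it took the 5 highest scores within 1 kb of an annotated transcription start site (TSS) in each list, and peaks at the TSS of the genes that were always named. Not every gene that the rule took is printed.

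Peak lists were compared with bedtools 2.31.1 at an overlap of at least 1 bp, with 95% Clopper-Pearson intervals and 1000 random placements within chromosomes. A gene had a promoter peak when a peak overlapped the 1 kb on each side of an annotated TSS of its build, mm10. Fisher's exact test, two-sided, compared genes with and without a promoter peak for calls in each direction over the 13069 tested genes with a position, with Benjamini-Hochberg adjustment over 24 tests. A Cochran-Mantel-Haenszel test in 10 bins of mean expression was run beside it.

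On simulated data made from these libraries with 200 changed genes, edgeR recovered 22.4%, 65.7% and 95.5% of genes changed 1.5-, 2- and 4-fold in the day 0 comparison. The corresponding shares were 16.4%, 67.2% and 93.9% at day 7, and 0 (1.5-fold), 28.4% and 87.9% for the interaction. Of the calls made on simulated data, 2.4% to 8.3% were false, and 0 of 40 random lists were called in each comparison by camera. The simulated genes varied independently of each other, so these lists could not show false calls that come from correlation between genes. In the real libraries the estimated correlation within a list reached 0.679. Far fewer genes were changed in the simulation than were called in the data. All 600 planted peak overlaps were found.

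Alternatives named before the data were examined were DESeq2-type size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter or a mean of at least 1 CPM, the replicate number as a block, the fit of only the 6 libraries compared, leaving out each library in turn, and for peaks a reciprocal overlap of 50%, a score of at least 100, the same number of top-scored peaks, 5 kb around the TSS and matching on expression. Summing the transcripts of a gene was added after the data were seen. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.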

Results

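The series addresses how LSD1, a histone demethylase encoded by Kdm1a, acts in the making of beige fat cells. The 12 RNA-seq libraries of mouse 3T3-L1 preadipocytes covered control cells and cells labelled as overexpressing LSD1, each at day 0 (confluent, before induction) and at day 7 of adipogenic differentiation, with 3 biological replicates per group. Total counts over all transcripts were 37032832 to 37565527 per library in control at day 0 and 27881281 to 31008490 in control at day 7. They were 34098249 to 36301893 in the group labelled as overexpressing LSD1 at day 0 and 27512273 to 30030309 at day 7. 4 peak lists of LSD1 and 2 of Nrf1, each from 1 ChIP-seq sample, completed the data. All values per gene are means over 3 replicates with their SD, and fold changes are log2 values with their standard error (SE). The libraries carrying the LSD1 overexpression label are called the labelled libraries, because the measured Kdm1a level, given next, did not pass as higher at day 0 and was lower at day 7. Every direction below is between labels. The sample titles do not say whether the replicates of a label came from separately derived lines. An effect of the label therefore cannot be told apart from another difference between the lines, and p-values cover the spread between replicates only.

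Kdm1a, the gene meant to be overexpressed, was not higher by the test in the labelled libraries at day 0 and was lower in them at day 7. Kdm1a (chromosome 4) stood at 83.13 ± 3.76 CPM (SD, n = 3) in control and 97.54 ± 7.47 CPM in labelled libraries at day 0, a log2 difference of 0.23 (SE 0.096, adjusted p = 0.0969, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and each of the 3 labelled libraries lay above each of the 3 control libraries. At day 7 the levels were 69.39 ± 4.50 CPM and 54.72 ± 0.606 CPM (n = 3), so Kdm1a fell by 0.34 on the log2 scale (SE 0.097, adjusted p = 0.00751, edgeR). The effect of the label differed between the days, with an interaction of −0.57 (SE 0.136, adjusted p = 0.00345, edgeR). Without replicate 1 of the labelled day 0 group, the day 0 difference was 0.29 and passed the test (adjusted p = 0.0131, edgeR). The fold at either day stayed under 1.5, and the counts cover RefSeq transcripts of the endogenous gene, so a construct without those sequences would not be counted.

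**Figure D1:**
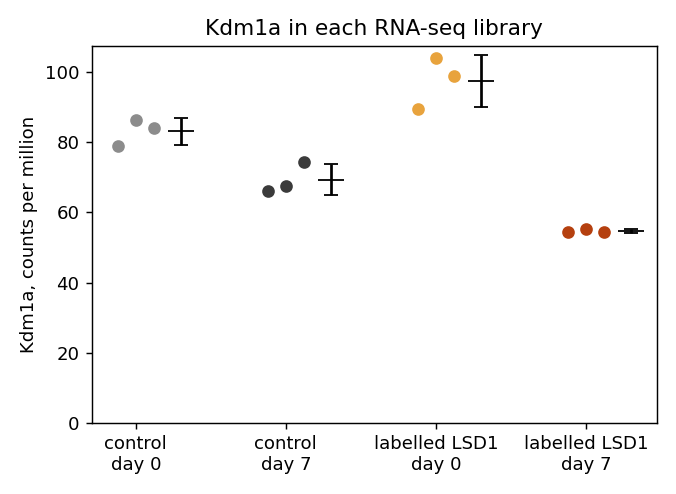
Kdm1a level in each of the 12 RNA-seq libraries, in CPM on a linear axis that starts at 0; points are libraries, and the bar beside each group is the mean with its SD (n = 3). The labelled day 7 libraries sit at 54.72 CPM, below the control day 7 libraries at 69.39 CPM.

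The first comparison, day 7 against day 0 in control cells, shows what differed with differentiation without the label. Its fold changes had a Spearman correlation of −0.308 with GC content across genes, and no trend on GC content was removed from the values given here. All 24 measured genes of the adipocyte program rose, by a median log2 fold change of 6.91 (6.81 with a gene at 0 counts set to its bound). Plin1, which coats lipid droplets, rose by 10.09 (SE 0.368, n = 3) from 0.225 to 250.5 CPM, Adipoq, the adipokine adiponectin, by 8.73 (SE 0.413), the glucose transporter Slc2a4 by 7.64 (SE 0.255), and Pparg, the master regulator of fat cell formation, by 1.78 (SE 0.136). Of 23 preadipocyte and fibroblast genes 20 fell and 1 rose, with a median of −1.43: the matrix protein Postn stood at −1.98 (SE 0.099) and the smooth muscle actin Acta2 at −4.38 (SE 0.272), while Pdgfra rose by 0.72 (SE 0.092). In total 6447 of 13356 genes passed the test, 3168 higher and 3279 lower.

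Genes of several metabolic groups rose with differentiation in control cells, and many others of the same groups did not pass. Of 79 nuclear genes of oxidative phosphorylation 40 rose, 4 fell and 35 did not pass, with a median of 0.55; Uqcrc2 of complex III rose by 1.28 (SE 0.109) and Atp5l fell by 1.19 (SE 0.284). Camera's call was lost with an estimated correlation (adjusted p = 0.583). Of 19 TCA cycle genes 18 rose, among them pyruvate carboxylase, Pcx, by 3.32 (SE 0.164). Fatty acid oxidation had 15 of 21 genes higher and 1, Cpt1a, lower, with Acadm higher by 2.32 (SE 0.129). Lipogenesis had 11 of 18 higher and 2 lower, with Agpat2 higher by 3.18 (SE 0.141) and Elovl6 at −1.02 (SE 0.173). Glycolysis had 10 of 16 higher, with Hk2 at 3.09 (SE 0.226). For fatty acid oxidation, lipogenesis and glycolysis the calls were lost as well (adjusted p = 0.247, 0.247 and 0.278 with an estimated correlation). The mitochondrial ribosome had 33 of 78 higher and 4 lower (median 0.30), and mitochondrial biogenesis 10 of 24 higher and 2 lower (median 0.44), with Ppargc1b higher by 2.71 (SE 0.234) and Ppargc1a, a coactivator of mitochondrial genes, by 0.96 (SE 0.253). These calls were lost too (adjusted p = 0.576 and 0.191 with an estimated correlation). Nrf1 passed the test with −0.39 (SE 0.140, adjusted p = 0.0347, edgeR), but not when any 1 of the 6 libraries was left out, where the adjusted p was 0.0558 to 0.0973.

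Many thermogenic, immune and cell cycle genes also passed in control cells, and others of these groups did not. Of 12 measured thermogenic genes 9 rose and 1 fell, with a median of 2.63 (2.32 with bounds): the potassium channel Kcnk3 rose by 4.42 (SE 0.278) and Gk by 2.09 (SE 0.156), while Acot11 fell by 1.60 (SE 0.454). Ucp1, the uncoupling protein of brown fat, Prdm16 and Cidea were below the filter, with 3, 2 and 18 counts in all 12 libraries together, so no difference was detectable at this depth. Interferon response had 12 of 19 genes higher and 0 lower (median 1.46), with the sensor Ifih1 at 3.48 (SE 0.390). Inflammation had 7 of 14 higher and 3 lower: Lcn2 rose by 7.99 (SE 0.244), complement C3 by 3.55 (SE 0.139), and Vcam1 fell by 2.18 (SE 0.122). Of 25 cell cycle genes 15 fell, such as Mcm4 by 1.12 (SE 0.137). Camera's calls for interferon response, inflammation and cell cycle were lost (adjusted p = 0.465, 0.185 and 0.505 with an estimated correlation). Among the largest rises, Zbtb16 was at least 1370-fold higher at day 7 (0 counts at day 0), Saa3 rose by 9.97 (SE 0.563), Cd36 by 9.70 (SE 0.514) and Hp by 9.05 (SE 0.303), and the matrix and contractile genes Col8a1 (−4.97, SE 0.355), Myl9 (−4.68, SE 0.321) and Tnc (−4.19, SE 0.326) were among the 10 largest falls.

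By camera with preset correlation, 13 lists passed in control cells. Adjusted over the list alone, the counts were 24 of 24 for the adipocyte program, 21 lower for fibroblast genes, 41 higher for oxidative phosphorylation, and 14 higher for interferon response. With an estimated correlation, the adipocyte (adjusted p = 0.0382), fibroblast (adjusted p = 0.00347), thermogenic (adjusted p = 0.0395) and TCA cycle lists (adjusted p = 0.0395) stayed under 0.05. The other calls were lost, as given above. Beige-selective (1 higher and 1 lower of 8), white-selective (7 and 3 of 13), LSD1 complex (2 and 2 of 17) and stress response genes (4 and 4 of 12) did not pass camera (adjusted p = 0.708, 0.119, 0.418 and 0.708). By fry, white-selective (adjusted p = 2.71e-05, limma) and LSD1 complex genes (adjusted p = 0.0369, limma) passed. Markers of macrophages, muscle, bone or cartilage and endothelium, with 3 to 5 measured members each, did not pass camera in any of the 5 comparisons over all 12 libraries. The macrophage list passed it for differentiation in labelled libraries without labelled day 0 replicate 2 (adjusted p = 0.034). By limma's fry, they passed lower in control differentiation for macrophage, bone or cartilage and endothelial markers (adjusted p = 0.0313, 0.000447 and 0.0144) and in labelled differentiation (7.29e-05, 1.59e-08 and 0.0363), where muscle markers passed higher (0.04). Macrophage and bone or cartilage markers also passed lower by fry at day 7 (adjusted p = 0.00615 and 5.87e-07) and in the interaction (0.0246 and 3.56e-06).

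Day 7 against day 0 in the labelled libraries had the same direction for most groups and larger medians, and 12 of the 14 list calls by camera were lost with an estimated correlation (adjusted p = 0.0539 to 0.294). All 24 adipocyte program genes rose (median 8.82, or 7.73 with bounds), with Slc2a4 going from 0.0482 to 300.7 CPM and Pparg at 3.39 (SE 0.145, n = 3). All 23 fibroblast genes fell (median −3.70), with Pdgfra at −3.91 (SE 0.104). All 79 oxidative phosphorylation genes rose (median 2.02), with Uqcrc2 at 2.83 (SE 0.114), and so did all 19 TCA cycle genes (median 2.54), with Idh3a at 3.96 (SE 0.115). Fatty acid oxidation had 20 of 21 higher (median 2.69), lipogenesis 14 of 18 higher and 2 lower (2.78), glycolysis 13 of 16 higher (2.84), the mitochondrial ribosome 70 of 78 higher and 1 lower (1.08), thermogenic genes 10 higher and 2 lower of 12 (3.34), and stress response genes 9 of 12 higher (0.91). Mitochondrial biogenesis had 18 higher and 3 lower of 24 (0.75). In contrast to control cells, all 19 interferon response genes fell (median −5.27), with Ifit2 at −4.00 (SE 0.151), and 11 of 14 inflammation genes fell and 3 rose (median −3.44), with Cxcl5 at −7.58 (SE 0.217). Of 25 cell cycle genes 23 fell (median −2.97), with cyclin Ccnd1 at −5.77 (SE 0.337).

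In the labelled libraries 9325 genes passed between the days, 4356 higher and 4969 lower. Of these, 2016 were also higher and 2141 also lower in control, against 1033.2 and 1219.9 for independent calls. A further 464 were lower in labelled libraries and higher in control, and 354 were higher in labelled libraries and lower in control. Across genes, which are not independent replicates, the fold changes of the 2 genotype labels had a Pearson correlation of 0.565. With an estimated correlation, only the fibroblast (adjusted p = 0.00422) and TCA cycle lists (adjusted p = 0.0448) of the 14 called stayed under 0.05. The others had adjusted p = 0.0539 for adipocyte and for thermogenic genes, 0.195 for oxidative phosphorylation, glycolysis, the mitochondrial ribosome and interferon response, 0.12 for fatty acid oxidation, 0.183 for lipogenesis, 0.0626 for mitochondrial biogenesis and inflammation, 0.289 for cell cycle and 0.294 for stress response. Beige-selective, white-selective and LSD1 complex genes did not pass camera (adjusted p = 0.562, 0.111 and 0.637), but all 3 passed by fry (adjusted p = 0.00148, 4.13e-06 and 0.00259, limma). Adjusted over the list alone, the counts were 24 of 24 for the adipocyte program, 79 of 79 for oxidative phosphorylation and 19 and 4 for mitochondrial biogenesis.

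**Figure D2:**
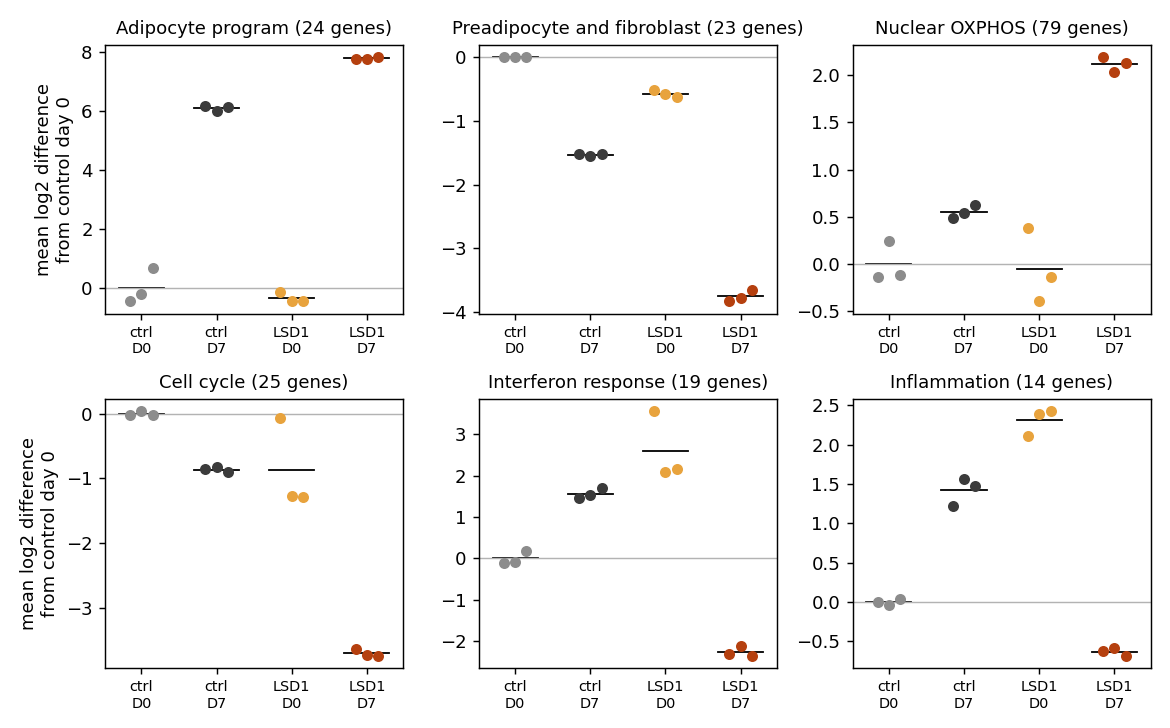
Mean log2 difference from control day 0 of 6 gene lists in each of the 12 libraries; each point is 1 library, lines are group means (n = 3), ctrl is control and LSD1 the labelled libraries, and the vertical axes differ between panels. In the labelled day 0 group, replicate 1 stands at 3.55 for interferon response, where the other replicates stand at 2.08 and 2.16.

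At day 0, before induction, many immune genes were higher and several matrix genes lower in the labelled libraries than in control. All 19 interferon response genes were higher, with a median log2 difference of 2.94: the antiviral gene Rsad2 by 4.44 (SE 0.418, n = 3), Ifi44 by 3.89 (SE 0.392) and the transcription factor Irf9 by 1.62 (SE 0.160). The list's camera call was lost (adjusted p = 0.248 with an estimated correlation), and replicate 1 of the labelled group stood at 3.55 where the others stood at 2.08 and 2.16. Of 14 inflammation genes 12 were higher and 0 lower, with a median of 1.89: the acute-phase gene Saa3 by 7.38 (SE 0.542), the chemokines Cxcl5 by 5.48 (SE 0.190; 8.85 ± 1.39 against 396.2 ± 34.0 CPM) and Cxcl1 by 3.89 (SE 0.175), and Lcn2 by 5.10 (SE 0.220). Of 23 fibroblast genes 13 were lower and 2 higher (median −0.69), with Postn at −1.88 (SE 0.098) and the collagen Col3a1 at −1.85 (SE 0.120), while Gata3, a brake on fat cell formation, was higher by 1.46 (SE 0.157) and Pdgfra by 0.51 (SE 0.092). Among the 10 largest falls were the elastin gene Eln (−5.25, SE 0.215), Clec3b (−5.79, SE 0.266) and Sema5a (−4.07, SE 0.222), and Fam107a was at least 9.16-fold lower in the labelled libraries, where it had 0 counts.

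Metabolic groups differed little at day 0. Of 79 oxidative phosphorylation genes 76 did not pass (1 higher, 2 lower; median −0.01), and the TCA cycle had 17 of 19 not passed and fatty acid oxidation 18 of 21, with 3 lower. Of 24 adipocyte program genes 3 were higher and 5 lower (median −0.56), with Plin4 at 0.70 (SE 0.097) and the regulator Cebpa at −1.62 (SE 0.170). G0s2 had 52 counts in control and 2 in labelled libraries (95% counting interval of the fold 7.23 to 233). Pparg stood at −0.25 (SE 0.134, adjusted p = 0.196, edgeR), Nrf1 at 0.19 (SE 0.139, adjusted p = 0.359, edgeR) and Ppargc1a at 0.45 (SE 0.252, adjusted p = 0.213, edgeR). Adipoq passed with −2.51 (SE 0.626) at levels near 1 CPM or less. Thermogenic genes had 3 higher and 1 lower of 12 (median 0.33): Pdk4 was higher by 2.28 (SE 0.253) and Ebf2, a factor of brown fat identity, lower with −2.28 (SE 0.238). Stress response genes had 8 higher and 2 lower of 12 (median 0.62), with Chac1 at 1.57 (SE 0.283) and Atf3 at 4.14 (SE 0.725). Cell cycle genes had 9 lower and 0 higher of 25 (median −0.73), with Mcm4 at −1.22 (SE 0.137). Both camera calls were lost (adjusted p = 0.778 each with an estimated correlation). Beige-selective genes had 4 higher and 0 lower of 8 (median 1.28), with Fgf21 at 0.0530 ± 0.0459 CPM in control and 1.956 ± 1.323 CPM in labelled libraries; the list did not pass camera (adjusted p = 0.324) and passed by fry (adjusted p = 0.0341, limma). White-selective genes had 0 higher and 1 lower of 13 (median −0.12), without passing camera (adjusted p = 0.604), and passed lower by fry (adjusted p = 0.00749, limma). Lipogenesis, glycolysis, mitochondrial biogenesis, mitochondrial ribosome and LSD1 complex genes did not pass camera with all libraries.

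At day 0 3448 of 13356 genes passed, 1709 higher and 1739 lower, and camera called interferon response, inflammation, fibroblast, cell cycle and stress response lists. Adjusted over the list alone, 19 interferon, 12 inflammation and 14 lower fibroblast genes passed, and 12 cell cycle genes were lower. With an estimated correlation, inflammation (adjusted p = 0.00302) and fibroblast genes (adjusted p = 0.0205) stayed under 0.05, while the other 3 did not, as given above. Replicate 1 of the labelled day 0 group stood apart: its correlation of log2 CPM with the other replicates was 0.955 and 0.957, where theirs was 0.993. Relative to control at day 0 it was at −0.07 for cell cycle (−1.27 and −1.29 in the other replicates), at 0.38 for oxidative phosphorylation (−0.39 and −0.14) and at 2.12 for inflammation (2.39 and 2.43). Its deviation from the mean of the other 2 replicates had a Spearman correlation with transcript length of −0.389, against 0.468 and 0.210 for the same measure in the other replicates. Within a group these deviations cancel out by construction, so opposite signs come with the measure and do not single out a replicate. Without labelled replicate 1, 6564 genes passed, oxidative phosphorylation became lower (median −0.34, adjusted p = 0.00722 by camera) and Nrf1 (0.35, adjusted p = 0.00668, edgeR) and Ppargc1a (0.75, adjusted p = 6.88e-05, edgeR) passed, and fatty acid oxidation passed lower by camera (−0.22, adjusted p = 0.0411). The mitochondrial ribosome list passed higher by camera without control replicate 2 (0.20, adjusted p = 0.00901) or labelled replicate 2 (0.18, adjusted p = 0.00379). Control replicate 2 had a correlation with length of −0.441, against 0.308 and 0.280 in the other controls, with signs tied in the same way, and stood at 0.245 for oxidative phosphorylation (−0.131 and −0.114). Control replicate 3 stood at 0.66 for the adipocyte program, the other controls at −0.44 and −0.22, and without it the day 0 median of that list was 0.03. Without control replicate 3 the count was 2174, and with only the 6 libraries compared it was 1862. The stress response call was lost without control replicate 1 (adjusted p = 0.0692), labelled replicate 2 (0.106) or labelled replicate 3 (0.144), and with fry (adjusted p = 0.0947, limma).

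At day 7 most measured genes of oxidative phosphorylation and the adipocyte program were higher, and most fibroblast genes lower, in the labelled libraries than in control. Of these 3 lists only the fibroblast list stayed under 0.05 by camera (adjusted p = 0.0095 with an estimated correlation), and the other 2 had 0.213 each. By fry, which does not compare a list with the other genes, all 3 passed. The adjusted p was 1.98e-05 for oxidative phosphorylation, 5.48e-06 for the adipocyte program and 4.07e-11 for fibroblast genes (fry, limma). Of 79 nuclear oxidative phosphorylation genes 77 were higher and 0 lower, with a median log2 difference of 1.45: Cox6a2, a subunit of complex IV, by 7.05 (SE 0.379, n = 3; 0.946 ± 0.161 against 125.9 ± 6.59 CPM) and Ndufv1 of complex I by 2.26 (SE 0.137). Of 24 adipocyte program genes 21 were higher and 2 lower (median 1.796), with Slc2a4 at 3.09 (SE 0.161), Agpat2 at 2.58 (SE 0.135) and Pparg at 1.36 (SE 0.134; 133.1 ± 6.08 against 341.5 ± 7.42 CPM). Of 23 fibroblast genes 19 were lower and 1 higher (median −2.22), with Pdgfra at −4.13 (SE 0.105; 1106 ± 38.8 against 63.19 ± 3.33 CPM) and Postn at −3.60 (SE 0.106). Among adipocyte genes, the resistin gene Retn (−1.45, SE 0.367) and the adrenergic receptor Adrb3 (−2.85, SE 0.494) were lower, and Adipoq was at 0.54 (SE 0.278, adjusted p = 0.107, edgeR). The Retn call was lost with the DESeq2 Wald test (−1.41, adjusted p = 0.353). Adipoq passed with limma-voom (0.54, adjusted p = 0.00693) and with only the 6 libraries compared (0.53, adjusted p = 5.93e-05, edgeR).

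Many genes of fuel use and stress response were higher at day 7 and many immune and cell cycle genes lower, but most of these list calls by camera were lost as stated below. The TCA cycle had 18 of 19 genes higher (median 1.57), with Pdhb at 2.26 (SE 0.096) and Idh3a at 1.88 (SE 0.105). Fatty acid oxidation had 20 of 21 higher (median 1.47), while Cpt1a, which controls the entry of fatty acids into mitochondria, was lower with −0.47 (SE 0.109). Lipogenesis had 12 of 18 higher and Elovl6 lower (median 1.59), with Me1 at 1.86 (SE 0.086), and glycolysis 14 of 16 higher and 1 lower (median 1.33), with Pfkp at 1.75 (SE 0.132). The mitochondrial ribosome had 69 of 78 higher and 1 lower (median 0.92), with Mrps18b at 1.75 (SE 0.121), and mitochondrial biogenesis 10 higher and 1 lower of 24 (median 0.35), with the nuclear receptor Esrra at 2.31 (SE 0.130). Of these 6 lists only the TCA cycle stayed under 0.05 (adjusted p = 0.0471 with an estimated correlation), with 0.172 for fatty acid oxidation, 0.159 for mitochondrial biogenesis and 0.213 for the other 3. Nrf1 (0.27, SE 0.141, adjusted p = 0.116, edgeR) and Ppargc1a (0.34, SE 0.250, adjusted p = 0.255, edgeR) did not pass. With only the 6 libraries compared both passed (0.25, adjusted p = 0.0427 for Nrf1, and 0.32, adjusted p = 0.027 for Ppargc1a, edgeR). Stress response genes had 11 of 12 higher (median 1.55), with Trib3 at 3.65 (SE 0.279) and Atf4 at 1.86 (SE 0.156). Of 19 interferon genes 17 were lower (median −3.73), with Ifit2 at −3.33 (SE 0.150), and of 14 inflammation genes 10 were lower and Lcn2 higher (median −2.09), with Cxcl5 at −4.49 (SE 0.199) and C3 at −2.42 (SE 0.132). Of 25 cell cycle genes 21 were lower and 1 higher (median −2.67), with the spindle checkpoint gene Bub1 at −5.91 (SE 0.338) and Top2a at −4.53 (SE 0.272). Inflammation stayed under 0.05 (adjusted p = 0.0471 with an estimated correlation), while stress response and interferon response (0.213 each) and cell cycle (0.271) did not.

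Thermogenic genes at day 7 had 8 of 12 members higher and 1 lower in the labelled libraries (median 2.03), with Cox7a1 at 4.18 (SE 0.276) and the coactivator Ppargc1b at 2.29 (SE 0.209), and the list's camera call was lost (adjusted p = 0.116 with an estimated correlation). Ucp1 had at most 1 count and Cidea at most 6 counts in any day 7 library, below the filter. Beige-selective genes went both ways (3 higher, 2 lower of 8), with Cited1 at 2.32 (SE 0.547), Tbx15 at −1.17 (SE 0.156) and Fgf21, a hormone of fasting, at 520 counts in labelled and 2 in control libraries, a ratio of 311 (95% counting interval 85.8 to 2580). White-selective genes had 4 higher and 7 lower of 13, with Psat1 at 1.99 (SE 0.106) and Nnmt at −1.90 (SE 0.159). LSD1 complex genes had 6 higher and 7 lower of 17, with Mta3 at 0.67 (SE 0.159) and Gse1 at −1.09 (SE 0.110). These 3 lists did not pass camera (adjusted p = 0.696, 0.696 and 0.686), while white-selective (lower, adjusted p = 0.0143, limma) and LSD1 complex genes (adjusted p = 0.004, limma) passed by fry. Among the largest rises outside the lists were the carotenoid oxygenase Bco1 (7.73, SE 0.305), Chchd10 of the mitochondrial intermembrane space (6.82, SE 0.225) and Depp1 (6.37, SE 0.455), and the hormone gene Ghrh rose from 3.343 to 147.3 CPM. Among the largest falls were the growth factor Ptn (−8.21, SE 0.208; 419.1 ± 29.1 CPM in control), Sfrp2 (44.73 against 0.0897 CPM) and Mmp9 (−7.97, SE 0.329), and P4ha3 was at least 174-fold lower with 0 counts in the labelled libraries.

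At day 7 8491 of 13356 genes passed, 4027 higher and 4464 lower, and 140 were over 8-fold higher and 870 over 8-fold lower. Camera called 14 lists. Adjusted over the list alone, 78 oxidative phosphorylation, 21 adipocyte and 70 mitochondrial ribosome genes were higher and 20 fibroblast genes lower. With an estimated correlation, 3 of them stayed under 0.05 and 11 were lost, as given above. In principal components of the 12 libraries, the labelled day 7 libraries lay farthest out on the first component (69.5% of the variance), at 140.14 to 142.54, with control day 7 at 2.89 to 5.25 and day 0 libraries at −79.50 to −64.94.

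**Figure D3:**
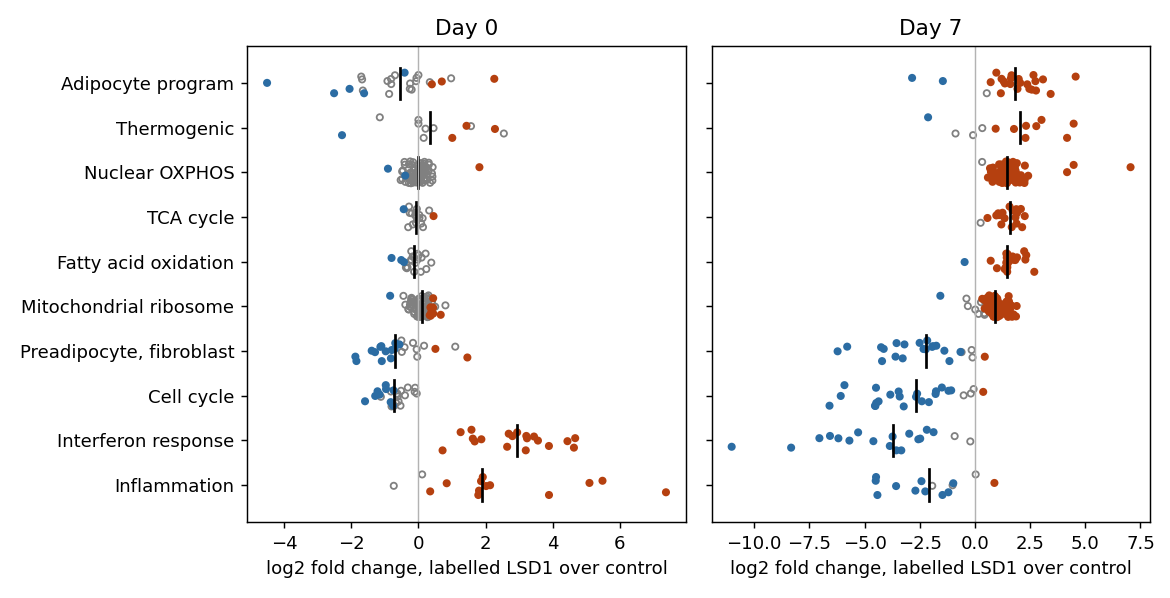
Fitted log2 fold change of each member of 10 gene lists, labelled libraries over control, at day 0 and day 7 (n = 3 per group); filled points passed the test at 0.05 (edgeR), open points did not, and black lines are list medians. Oxidative phosphorylation has a median of −0.01 at day 0 and 1.45 at day 7, and interferon response 2.94 and −3.73.

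The interaction asks whether the effect of the label differed between the days, and many genes of the groups named above passed it. Oxidative phosphorylation moved up by a median of 1.51 (69 of 79 genes passed, 0 in the other direction), with Cyc1 at 2.53 (SE 0.213) and Ndufv1 at 2.18 (SE 0.188, n = 3). Its camera call was lost (adjusted p = 0.254 with an estimated correlation), and so were those of the adipocyte program and of interferon response (adjusted p = 0.197 each). The adipocyte program had 17 higher and 1 lower of 24 (median 2.69), with Pparg at 1.61 (SE 0.189), Cebpa at 2.80 (SE 0.232) and Adipoq at 3.05 (SE 0.685). Interferon response turned from higher to lower, with 19 of 19 genes passed (median −7.17) and Irf9 at −4.10 (SE 0.236), and so did inflammation with 12 of 14 (median −4.39) and Cxcl5 at −9.98 (SE 0.273). Fibroblast genes had 17 lower and 2 higher of 23 (median −1.72), with Pdgfra at −4.64 (SE 0.137), Col1a1 at −3.11 (SE 0.185) and Col3a1 at 0.70 (SE 0.165). Nrf1 (0.08, SE 0.198, adjusted p = 0.756, edgeR) and Ppargc1a (−0.11, SE 0.354, adjusted p = 0.81, edgeR) did not pass. Without replicate 1 of the labelled day 0 group Ppargc1a passed with −0.41 (adjusted p = 0.0433, edgeR).

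Further groups passed in the interaction: TCA cycle (18 of 19 higher, median 1.39, Idh3a at 2.32, SE 0.147), fatty acid oxidation (19 of 21 higher, 1.77, Decr1 at 2.32, SE 0.137), lipogenesis (12 higher and 3 lower of 18, 1.47), glycolysis (12 of 16 higher, 1.14, Slc2a1 at 1.72, SE 0.185), mitochondrial ribosome (60 of 78 higher, 0.89), mitochondrial biogenesis (10 higher and 1 lower of 24, 0.35, Esrra at 1.95, SE 0.179), thermogenic (4 of 12 higher, 1.05), stress response (8 of 12 higher, 0.99) and cell cycle (17 lower and 2 higher of 25, −1.99, Bub1 at −4.94, SE 0.416). Bco1 (7.64, SE 0.552), Chchd10 (7.20, SE 0.333) and Ephx2 (6.50, SE 0.496) were among the 10 largest rises, and Il1rn (−13.66, SE 1.172), Oasl2 (−9.42, SE 0.825) and Ifit1 (−9.25, SE 0.645) among the 10 largest falls. In all 6933 genes passed, 3186 higher and 3747 lower. Of the 14 lists called, fibroblast (adjusted p = 0.0277), TCA cycle (adjusted p = 0.0449) and inflammation (adjusted p = 0.0083) stayed under 0.05 with an estimated correlation. Beside those given above, the others had adjusted p = 0.197 for thermogenic, fatty acid oxidation and mitochondrial biogenesis genes, 0.254 for lipogenesis and mitochondrial ribosome, 0.306 for glycolysis, 0.458 for cell cycle and 0.326 for stress response. Without replicate 1 of the labelled day 0 group the thermogenic (adjusted p = 0.115) and mitochondrial biogenesis calls (adjusted p = 0.126) were lost by camera. Beige-selective, white-selective and LSD1 complex genes did not pass camera (adjusted p = 0.871, 0.807 and 0.949), and adjusted over the list alone 70 oxidative phosphorylation genes passed.

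The fold changes of the label at day 0 and at day 7 had little correlation, while genes lower at both days, Postn among them, were more than independent calls would give. Across 13356 genes, which are not independent replicates, the fold changes of the 2 days had a Pearson correlation of 0.039 and a Spearman correlation of 0.079; the comparisons share no library. Genes higher at both days numbered 600 (515.3 for independent calls) and genes lower at both days 902 (581.2; odds ratio 2.44), among the latter Postn and the replication gene Mcm4 (−1.22 at day 0 and −1.76 at day 7). A further 629 genes were higher at day 0 and lower at day 7, and 385 the reverse.

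Genes of chromosome 16 stood lower in the labelled libraries at both days. Its 415 tested genes had a median log2 difference of −0.295 at day 0 and −0.317 at day 7, and 73.3% and 65.3% of them had negative values. With a trend on transcript length and GC content removed, the medians were −0.304 and −0.185. Each of the 6 labelled libraries had a negative chromosome 16 median, from −0.257 to −0.381. Chromosome 19, with 488 genes, had the highest medians, 0.181 and 0.430, and chromosome X stood at −0.052 and −0.488. Chromosome 16 was picked from 20 chromosomes after the values were seen.

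**Figure D4:**
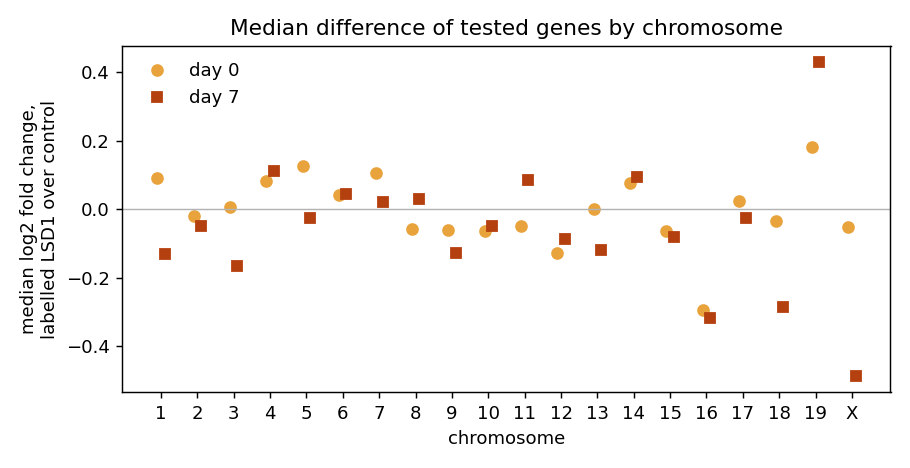
Median log2 fold change of the tested genes of each chromosome, labelled libraries over control; circles are day 0 and squares day 7. Chromosome 16 is at −0.295 and −0.317, without removal of a trend on length and GC content.

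LSD1 peak lists were larger in the labelled cells, at promoters and even more so elsewhere. Control cells had 3024 LSD1 peaks at day 0 and 8303 at day 7, and the labelled cells 13997 and 27221. Median widths were 1216.5 bp (day 0) and 1141.0 bp (day 7) in control lists, and 1695.0 and 707.0 bp in labelled lists. The lists covered 4.1 and 10.65 Mb in control cells, and 30.05 and 25.95 Mb in labelled cells. The labelled day 7 list thus held more but narrower peaks than the labelled day 0 list, and covered less. Peak numbers and promoter shares can depend on peak width, which was not tested. The share of peaks within 1 kb of a TSS was 86.5% (95% Clopper-Pearson interval 85.2 to 87.7) and 84.5% (83.7 to 85.3) in control cells, and 60.6% (59.8 to 61.4) and 40.2% (39.6 to 40.8) in labelled cells, against 2.71% to 3.8% for random placements. Promoter peaks numbered 2616 and 7018 in control cells and 8479 and 10934 in labelled cells, so the lower shares came with more promoter peaks. Among the highest-scored peaks that reached within 1 kb of a TSS were those at Banp, Zfp36l2 and Brd2 in control at day 0, at Brd2 and the lipid droplet gene Plin4 in control at day 7, at Vim, Chd2 and Phlda3 in labelled cells at day 0, and at Eef1a1, Ddhd2 and Mt2 in labelled cells at day 7. The 5 taken in control at day 7 were tied at the top score of 3100.0. Some of these peaks were wide, with a midpoint 5087 bp from the TSS at Plin4 and 4829 bp at Vim. All 4 LSD1 lists had a peak at the Nrf1 promoter, and Pparg and Ppargc1a had one in each list but that of control at day 0. A peak at the Adipoq TSS and one at Kdm1a itself (chromosome 4, 136602084 to 136603050, mm10) appeared only in the list of labelled cells at day 7. Each condition had 1 list of unknown depth, so these numbers were not tested between conditions.

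Control LSD1 peaks overlapped the longer LSD1 lists, and less so when the lists were made equally long. Of control day 0 peaks 84.4% (83.0 to 85.6) overlapped control day 7 peaks and 90.6% (89.5 to 91.7) overlapped peaks of labelled cells at day 0. Of control day 7 peaks 97.3% (97.0 to 97.7) overlapped peaks of labelled cells at day 7, and of labelled day 0 peaks 75.2% (74.4 to 75.9) did, against 1.0% to 3.08% in 1000 random placements of these pairs. With the same number of top-scored peaks in both lists, these overlaps were 48.8%, 39.8%, 61.9% and 47.2%. Nrf1 had 2078 peaks at day 0, of which 65.4% (63.4 to 67.5) lay at a TSS, and 1629 at day 7, with 90.8% (89.3 to 92.2). The highest promoter peaks were at Armc6, B3galt6 and Angptl6 at day 0 and at Upf1, Phf12 and Safb2 at day 7, and Nrf1 had a peak at its own promoter in the day 7 list. Of Nrf1 day 0 peaks 48.8% (46.6 to 51.0) overlapped day 7 peaks, and 62.2% (59.8 to 64.5) the other way. Many Nrf1 peaks overlapped LSD1 peaks, and the share rose with the length of the LSD1 list. Of Nrf1 day 0 peaks 23.6% (21.8 to 25.5) overlapped control and 65.0% (62.9 to 67.1) labelled LSD1 peaks at day 0. The same Nrf1 day 0 peaks overlapped control LSD1 peaks of day 7 in 57.8%. Of Nrf1 day 7 peaks 80.1% (78.1 to 82.0) overlapped control and 98.2% labelled LSD1 peaks at day 7. Random placements gave under 3%, but they do not allow for the many peaks of both factors at promoters. At day 0 33.5% of Nrf1 promoter peaks and 4.9% of its other peaks overlapped control LSD1 peaks, and 88.8% and 19.9% overlapped labelled LSD1 peaks. At day 7 the shares were 83.2% and 50% with control LSD1 peaks, and 99.4% and 86.7% with labelled LSD1 peaks. For scale, the share of all tested genes with an LSD1 promoter peak was 22.7% (control) and 70.7% (labelled) at day 0. It was 59.2% (control) and 80.2% (labelled) at day 7.

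**Figure D5:**
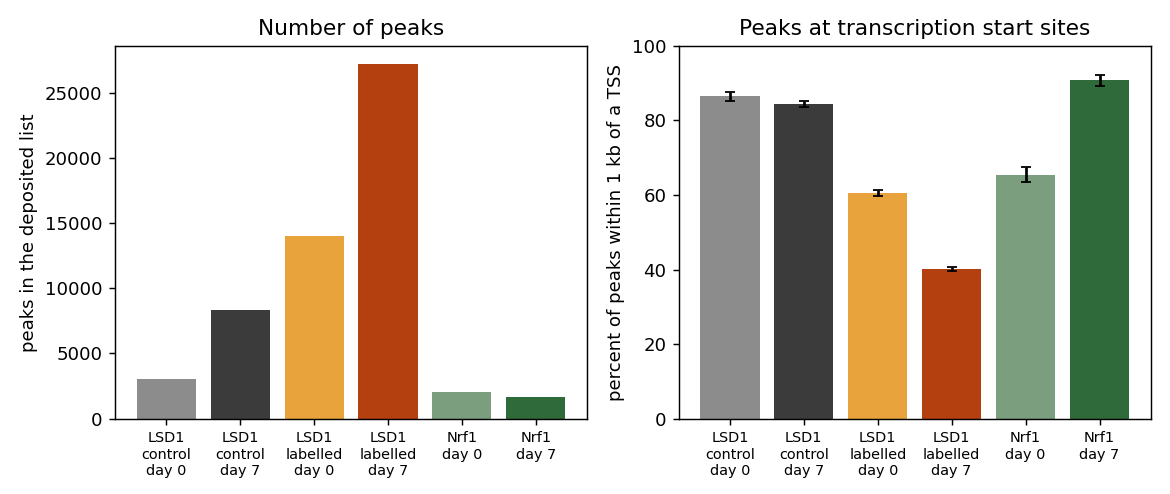
Left, number of peaks in each of the 6 deposited lists; right, percent of peaks within 1 kb of a TSS with 95% Clopper-Pearson intervals, which cover counting error only (1 list per bar). At day 7 the LSD1 lists hold 8303 peaks in control and 27221 in labelled cells, with 84.5% and 40.2% at a TSS.

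Genes with an LSD1 promoter peak at day 7 were more often higher and less often lower in the labelled libraries at day 7. Of the 7737 tested genes with a control day 7 LSD1 peak, 35.8% were higher, against 22.6% of genes without one (odds ratio 1.91, 95% interval 1.76 to 2.06, BH-adjusted p = 1.28e-58, Fisher's exact test), and 26.5% against 43.2% were lower (odds ratio 0.48). For peaks of labelled cells the odds ratios were 2.67 (2.38 to 2.99) for higher and 0.44 (0.40 to 0.48) for lower genes. Matched on mean expression, the odds ratios for higher genes were 1.25 and 1.44 (adjusted p = 2.1e-06 and 5.96e-07, Cochran-Mantel-Haenszel test). At day 0 genes with an LSD1 peak in labelled cells were less often higher (odds ratio 0.65) and less often lower (0.85; matched 0.45). For day 7 against day 0 in labelled cells, the odds ratios were 2.3 for higher and 0.41 for lower genes with the day 7 peaks of those cells. Genes with an Nrf1 day 7 promoter peak were more often higher at day 7 (odds ratio 1.32, 1.19 to 1.48), which was 1.09 and not past the threshold when matched on expression (adjusted p = 0.13), and less often lower (0.54). Of 1559 tested genes with an Nrf1 day 0 promoter peak 36.0% also had a control LSD1 peak at day 0 (odds ratio 2.13, 1.90 to 2.39), and of 1698 with a day 7 peak 84.2% had a control LSD1 peak at day 7 (4.28, 3.74 to 4.92). The remaining pairs of peak list and comparison, of 24 in all, had odds ratios of 0.53 to 1.35. Matched on expression, 6 of these turned from over 1 to under 1. For labelled day 0 peaks and genes higher with differentiation in labelled cells, 1.35 became 0.87 (adjusted p = 0.00902, Cochran-Mantel-Haenszel test). For control day 0 peaks and genes lower with differentiation in control, 1.23 became 0.98.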

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

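The tests of the share of differentiated cells, of swapped labels and of peak numbers were chosen only after the results were seen, while the length and GC test at day 7 was written down before. A difference in the effect of the label between day 0 and day 7 brought up the results of this paragraph and the next, for genes by the interaction test of edgeR and for lists by camera on that interaction. Kdm1a had an interaction of −0.57, Pparg of 1.61 and Adipoq of 3.05, and 6933 genes passed in all. Most of the Adipoq value came from its lower day 0 level at few counts, and the adipocyte list median also depended on day 0, as given above. With preset correlation, medians of lists that passed were 2.69 for the adipocyte program, 1.51 for oxidative phosphorylation, 1.39 for the TCA cycle, 1.77 for fatty acid oxidation, 1.47 for lipogenesis, 1.14 for glycolysis, 0.35 for mitochondrial biogenesis, 0.89 for the mitochondrial ribosome, 1.05 for thermogenic genes and 0.99 for stress response genes.

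Negative list medians were −1.72 for fibroblast genes, −1.99 for cell cycle, −7.17 for interferon response and −4.39 for inflammation. Of these 14 lists, only fibroblast (adjusted p = 0.0277), TCA cycle (0.0449) and inflammation (0.0083) passed with an estimated correlation. The other 11 did not, at an adjusted p of 0.197 for adipocyte, thermogenic, fatty acid oxidation, mitochondrial biogenesis and interferon genes, 0.254 for oxidative phosphorylation, lipogenesis and mitochondrial ribosome, 0.306 for glycolysis, 0.326 for stress response and 0.458 for cell cycle. Of 200 splits of the libraries 100 were run, the real one and 99 drawn at random, and only the real one called 6933 or more genes for the interaction. The 6 others that kept the 2 day 7 groups apart, 1 of them with their labels exchanged, called 4995 to 6127, and the rest at most 25. A random assignment of the libraries was thus argued against for that count, which mostly reflects the day 7 difference. For the comparisons of 3 against 3 libraries only 10 splits exist, too few for a share under 0.05. The real one was the only 1 of 10 to call 6447 genes for differentiation in control (highest other 0), 9325 in labelled libraries (highest other 0), 3448 at day 0 (highest other 1) and 8491 at day 7 (highest other 0).

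Kdm1a did not pass as higher in the labelled libraries at day 0, where all 3 lay above all 3 controls, and was lower in them at day 7. Swapped genotype labels would put at least 1.5 times as much Kdm1a in the libraries labelled control at both days, and the larger ratio of group means was 1.27, at day 7. That decides nothing on a swap, because a construct outside the counted transcripts would leave the ratio near 1 under either labelling. Extra LSD1 from such a transcript was left open too: LSD1 peak numbers were 3.28 times as high in labelled cells at day 7 and 4.63 times at day 0, where the Kdm1a ratios were 0.79 and 1.17. With 1 list each of unknown depth, this explanation and a difference in ChIP depth cannot be told apart.

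At day 7 the oxidative phosphorylation, adipocyte and fibroblast lists differed between the labels. Transcript length and GC content were argued against, since at least 80.8% of each list median was kept after their trend was removed (oxidative phosphorylation 1.17, and 91.0% and 98.0% for the adipocyte and fibroblast lists). If only the share of differentiated cells differed, each list would imply the same share. The first test gave median shares of 14.4% and 28.7% for oxidative phosphorylation and adipocyte genes and of 74.5% to 77.7% by replicate for fibroblast genes, a gap of 60.6 points, but it assumes that undifferentiated cells at day 7 keep the day 0 profile and decides nothing, so a second version was chosen after its result was seen: among 14 adipocyte genes over 50-fold higher at day 7, the interquartile range of the label effect was 4.3 times the median SE, only slightly over the bound of 4, with quartiles of 1.64 and 2.74 and a range from −1.45 (Retn, whose call DESeq2 did not give) to 4.57. The second version assumes that all differentiated cells have 1 common profile, which was not measured, so it decides nothing on the share alone either. An effect of the label on gene regulation in fat cells was not tested apart from the share.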

How the results depend on the processing

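Of 75 counts of genes called under an alternative, 72 stayed within 1.5 times the main count. Of 5624 values of named genes 5431 kept direction and side of the threshold, 179 were no longer past it, 10 came past it and 4 turned direction; for lists the numbers were 1074, 52, 25 and 25 of 1176. The day 0 count was 1862 with only the 6 libraries compared. With an estimated correlation, camera called 4 lists for differentiation in control and 2 in labelled libraries. It called 2 at day 0, 3 at day 7 and 3 for the interaction. The preset value assumes a low correlation, but the size of the correlation was not the only difference between these settings. For fibroblast genes the estimate was 0.00792, below the preset 0.01, yet their day 7 adjusted p went from 9.41e-08 to 0.0095 (camera). Inflammation, with an estimate of −0.00629, went from 0.0401 to 0.185 in control differentiation (camera). With fry, 84 of 105 list results kept their side of the threshold, 20 came past it and 1 was lost. The lost one was stress response at day 0, so the other lists that camera called with preset correlation also passed by fry. For none of the changes was the cause tested. Alternatives with another pseudocount did not apply to the gene tests, as the files hold counts. The list tests used a prior count of 2, and no other value was run. Summing transcripts was chosen after seeing the data. At this depth Ucp1, Prdm16 and Cidea stayed below the filter, and for ChIP-seq the depth is unknown.

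With the replicate block, the counts were 6031, 9051, 2964, 8161 and 6541 for differentiation in control, in labelled libraries, day 0, day 7 and the interaction, Kdm1a stood at 0.229 (day 0) and −0.341 (day 7), and LSD1 complex genes in the interaction had a median of 0.160 with the direction of camera turned. Replicate numbers did not pair the libraries: residual correlations of 18 pairs were −0.249 to 0.114, and 2 of 12 libraries were most alike to those with their own number.

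Leaving out 1 library gave these lowest and highest values: day 0 count 2174 and 6564, day 7 7660 and 7890, differentiation in labelled libraries 8790 and 10294, in control 5250 and 5505, interaction 6307 and 8754; Kdm1a 0.180 and 0.288 at day 0 (0.288 passed) and −0.375 and −0.287 at day 7; correlation of both days 0 and 0.091; lists called 4 and 7 at day 0, 14 and 14 at day 7, 13 and 13, 14 and 15, and 12 and 14 for the others. For these results, none of them called before, the sign of the median or log2 value or only the direction of camera turned: Nrf1 (−0.079, 0.179) and Ppargc1a (−0.410, 0.123) in the interaction; at day 0 adipocyte (−0.742, 0.031), glycolysis (−0.173, 0.296), mitochondrial ribosome (−0.029, 0.195), oxidative phosphorylation (−0.344, 0.149), macrophage (−0.267, 0.258), bone or cartilage (−0.308, 0.000) and endothelial lists (0.001, 0.720); endothelial at day 7 (−0.368, 0.019) and in the interaction (−0.801, 0.444); beige-selective in control (−0.206, 0.363) and in the interaction (−1.129, −0.834, against −0.30 with all libraries); LSD1 complexes in the interaction (−0.086, 0.199).

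Peaks at a score of at least 100 numbered 751 and 5229 (LSD1 control, day 0 and 7), 17078 (labelled day 7), 598 and 876 (Nrf1). Percent overlap with a reciprocal 50%, a score of 100 and the same number of top peaks was 77.2 (reciprocal) and 48.8 (top) for control day 0 in day 7; 58.7, 89.3 and 39.8 for control in labelled day 0; 87.1, 99.1 and 61.9 for control in labelled day 7; 50.3, 80.6 and 47.2 for labelled day 0 in day 7. For Nrf1 it was 74.9 (score) for day 0 in day 7 and 51.1 (score) the other way; 18.3 and 10.7 (score) for day 0 in LSD1 control; 67.3 and 62.7 (score) for day 7 in LSD1 control; 78.1 (reciprocal) in labelled day 7. Matching on expression turned 6 of 24 odds ratios from over 1 to under 1, the first 6 given next. Odds ratios matched on expression were 0.87 (LSD1 control day 0, lower at day 0), 0.98 and 0.68 (LSD1 control day 0 and day 7, lower with differentiation in control), 0.87 (labelled day 0, higher with differentiation), 0.89 and 0.86 (Nrf1 day 0, lower at day 0 and lower with differentiation), 1.09 (Nrf1 day 7, higher at day 7) and 0.8 (Nrf1 day 7, lower with differentiation). At a score of 100 they were 0.91 (LSD1 control day 0, lower at day 0), 0.89 (LSD1 control day 0 and Nrf1 day 7, higher with differentiation), 0.77 and 1.21 (Nrf1 day 0, higher and lower with differentiation), and with 5 kb 0.87 (Nrf1 day 0, higher).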

Other observations

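The families, the motif counts, the promoter counts of oxidative phosphorylation genes and the chromosome tests below were chosen only after the values were seen, except that the length and GC test of chromosome 16 was written down before it was run. Peroxisome and coenzyme Q genes were higher in the labelled libraries at day 7: 15 of 16 Pex genes (median log2 difference 0.99; Pex19, Pex14) and 11 of 11 Coq genes (median 1.08; Coq9, Coq5) passed higher and 0 lower. Of 27 collagen genes 21 were lower and 2 higher (median −1.50; Col1a1, Col1a2), of 12 Adamts protease genes 11 lower and 1 higher (−2.92), and of 341 Zfp genes 220 lower and 28 higher (−0.81). The interferon-inducible Gbp genes were higher at day 0 in 9 of 10 (2.19; Gbp6, Gbp2) and lower at day 7 in 9 of 10 (−4.08). These were picked from 155 families of gene symbols; camera with preset correlation passed each (adjusted p = 5.51e-05 for Pex, 0.000377 for Coq, 2.22e-05 for Col, 0.000802 for Adamts, 1.07e-06 for Zfp, and 5.61e-06 and 0.00106 for Gbp at day 0 and day 7). With an estimated correlation none did (adjusted p = 0.226, 0.439, 0.315, 0.303, 0.588, 0.677 and 0.588).

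Nrf1 peaks held the sequence GCGCATGCGC, a known core of the Nrf1 site, in 10.1% (95% Clopper-Pearson interval 8.8 to 11.5) of the day 0 list and 15.4% (13.7 to 17.3) of the day 7 list, against 0.0% and 0.3% of flanks and 2.9% of promoters of tested genes. LSD1 lists held it in 1.4% to 3.2% of peaks. Of 79 oxidative phosphorylation genes, 23 (29.1%) had an Nrf1 day 7 promoter peak, against 13.0% of all tested genes (BH-adjusted p = 0.00284, Fisher's exact test), and 77 had an LSD1 promoter peak in labelled cells at day 7, against 80.2% of all tested genes (adjusted p = 0.000701, Fisher's exact test). The control LSD1 lists did not pass: 55 of the 79 against 59.2% of all tested genes at day 7 (adjusted p = 0.205, Fisher's exact test), and 13 against 22.7% at day 0 (adjusted p = 0.438). At day 0 Nrf1 (19 of 79, adjusted p = 0.0238) and labelled LSD1 promoter peaks (72 of 79, adjusted p = 0.000701) passed as well. Labelled LSD1 peaks at day 7 were not particular to this list. They lay at 78 of 78 mitochondrial ribosome genes (adjusted p = 8.16e-06, Fisher's exact test) and 19 of 19 TCA cycle genes (adjusted p = 0.112). Beyond mitochondrial lists, they lay at 16 of 16 glycolysis, 17 of 17 LSD1 complex and 24 of 25 cell cycle genes. Several lists lay below the 80.2% of all tested genes, such as interferon response with 7 of 19. None of these tests was matched on mean expression.

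Chromosome 16 genes were lower in the labelled libraries at both days, a pattern picked from 20 chromosomes. Of rotations of the gene order 0.08% gave a run as low at both days. That share leaves the choice of chromosome out and decides nothing. A test added for that choice shuffled 10 Mb blocks 10000 times and took the most extreme of 20 chromosomes in either direction. With the real order counted 0.01% were as extreme, the lowest share it can give. That argued against chance placement only for values with the trend on length and GC content left in. No shuffle was run with that trend removed, where chromosome 19 stood at 0.185 (day 0) and 0.427 (day 7). For chromosome 16, removing the trend took the day 7 median from −0.317 to −0.185 and the day 0 median from −0.295 to −0.304. The higher one, −0.18, was beyond the bound of −0.15 by a small margin, which argued against that trend as the whole of the pattern, while part of the day 7 value went with it. A lower copy number in the labelled cells stays open: 100% of the 10 Mb windows (10 of 10) had a negative median at both days, but the chromosome was picked for low medians, and 85.7% of the windows of chromosome 19 were higher at both days, and DNA was not measured.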
